A study of Bos taurus with 16 samples.

How the data were processed

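RNA sequencing was used to measure transcript abundance in the mammary fat pad of newborn Holstein heifers, the tissue into which the gland's epithelium later grows. The calves had been gestated under heat stress or under cooling for the final stretch of pregnancy, 54 ± 5 days, during a summer in the subtropics. The series text gives 6 calves per group, whereas 8 libraries per group were listed; every listed library was used. The series text calls the samples calves but does not tie each library to an animal, so p-values measure the spread between these libraries. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy Plus Universal Mini kit and libraries were made with the NEBNext Ultra II RNA kit.

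Each library came as its own table of 37925 Ensembl transcripts with 5 columns, namely name, length, effective length, TPM and number of reads. Per the file headers, the last column holds estimated counts of reads per transcript, which need not be whole because reads shared between transcripts were divided among them. The deposited TPM values, per the file headers, are the same estimates scaled by effective length so that each library has the same total. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.40, cutadapt, STAR 2.7.10a, R 4.3.1, DESeq2 1.38.3 and the build ARS-UCD1.2, with no role or order. The quantifier and the annotation release are not given in the sources used here; the column names are those Salmon writes. Effective lengths were identical in all 16 files, so no correction fitted to a single library entered the TPM. The shortest transcript of the abundant block described in the results, 201 nt long, had an effective length of 10.01 nt. It took 0.104% to 0.521% of counts but 8.45% to 29.8% of TPM, and shares of counts were therefore preferred to shares of TPM.

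The files do not pair transcript IDs with gene names. The RefSeq gene table at hand, for assembly ARS-UCD2.0, matched 0 of the 37925 IDs. Transcripts were therefore not summed to genes, the 45 gene lists fixed before the data were examined were not tested, and the rule for named genes (largest fold changes among symbol-bearing genes past the threshold, plus list members) could not be applied. In its place the 2 higher and the 2 lower transcripts with the smallest p and a mean log2 CPM of at least 0 are named. That replacement was chosen after the files were seen.

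All pairs of files were compared. The files of cooled replicates 1 and 2 held identical values, 1 such pair of 120. In every other pair the chi-square of counts per degree of freedom was at least 77.0. The identical files were counted as 1 library, which left 7 cooled and 8 heat-stressed libraries. Totals ran from 40573338 to 55317188 estimated counts per library. A count of 0 in a library allows up to 3 counts, or 0.0542 to 0.0739 CPM. Wilson 95% intervals on the share of counts in the block were at most 0.0139 percentage points to each side. Such intervals and floors cover counting error alone, because PCR copies are not independent molecules.

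Estimated counts were rounded to whole numbers, which changed the total by 7.3e-05%. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3; TMM scaling, filterByExpr, robust fit, no covariates, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter kept 19180 of the 30617 transcripts with any count, and these held 99.8% of counts. Principal components were taken from log2 CPM (prior count 2) of the 500 most variable tested transcripts. Library measures were compared by two-sided exact permutation tests over all 6435 assignments of the 15 libraries, adjusted over 10 measures. Set tests used camera and fry (limma 3.58.1). Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

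The edgeR step was tested on simulated counts for the same 19180 transcripts and library sizes. It recovered 17 of 50 transcripts changed 2-fold, 24 of 50 changed 4-fold, 41 of 50 changed 8-fold and 40 of 50 changed 16-fold, with 5 false calls among 127. DESeq2 1.42.0 on the same simulated counts recovered 142 of the changed transcripts with 62 false calls. Each simulated transcript was drawn independently of the others, so the simulation held no structure shared between libraries. These rates therefore need not hold for the real comparison.

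Alternatives fixed before the data were examined were DESeq2, limma-voom with and without quality weights, 3 other scalings, no filter and a stricter filter on low counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0), other thresholds, other sets of variable transcripts and, for the transcript tests, leaving out each library. Those added after seeing the data kept both identical files, tested whole-number transcripts alone (within a tolerance of 0.0005), applied edgeR's filter to DESeq2, asked for transcripts above 0 in at least 8 libraries, gave the shared file the number 2 in the block, left out each library for the principal components, or left out the block or the pair of cooled replicate 4 and heat-stressed replicate 6. All results on the block, including its choice, were added after seeing the data. Expected results under no difference were counted from 100 splits of the 15 libraries with edgeR and 40 with DESeq2. After the data were seen, each of the 56 exchanges of 1 cooled and 1 heat-stressed label, and each of the 56 such pairs left out, was also fitted with edgeR.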

Results

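The mammary fat pad of newborn Holstein heifers was profiled by RNA sequencing in calves gestated under heat stress and in calves gestated under cooling late in pregnancy. After the identical files of cooled replicates 1 and 2 were counted as 1 sample, 7 cooled and 8 heat-stressed libraries were compared. Library totals were 47382776 ± 4946887 estimated counts in the cooled group (SD, n = 7) and 46462475 ± 3412821 in the heat-stressed group (SD, n = 8), with an exact permutation p of 0.679. The cooled libraries held 21613 ± 824 transcripts with at least 1 count and the heat-stressed libraries 21847 ± 814 (SD; exact permutation p = 0.583).

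The first comparison asked which transcripts of the fat pad differed between heat-stressed and cooled gestation. None of the 19180 tested transcripts passed the threshold in edgeR's quasi-likelihood test, where the smallest Benjamini-Hochberg adjusted p was 0.996. At an unadjusted p under 0.05 there were 436 transcripts, 188 higher and 248 lower in heat-stressed calves, against 959 at a nominal rate with no difference and a median of 519 over other splits of the same libraries. Limma-voom also gave 0, and DESeq2 without a filter on low counts gave 57, of which 53 were above 0 in under 8 of the 15 libraries. The spread between libraries was wide, with a biological coefficient of variation of 70.8%. On the 5894 tested transcripts with whole-number estimates it was 47.9%. How much of the wider spread comes from dividing shared reads between transcripts was not tested. The unadjusted count ran from 253 without heat-stressed replicate 4, 273 without cooled replicate 3 and 279 without heat-stressed replicate 5 to 908 without cooled replicate 4 and 2024 without heat-stressed replicate 6. The median standard error was 0.37 on the log2 scale, and the median 95% confidence interval reached 1.71-fold to each side of the estimate.

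**Figure D1:**
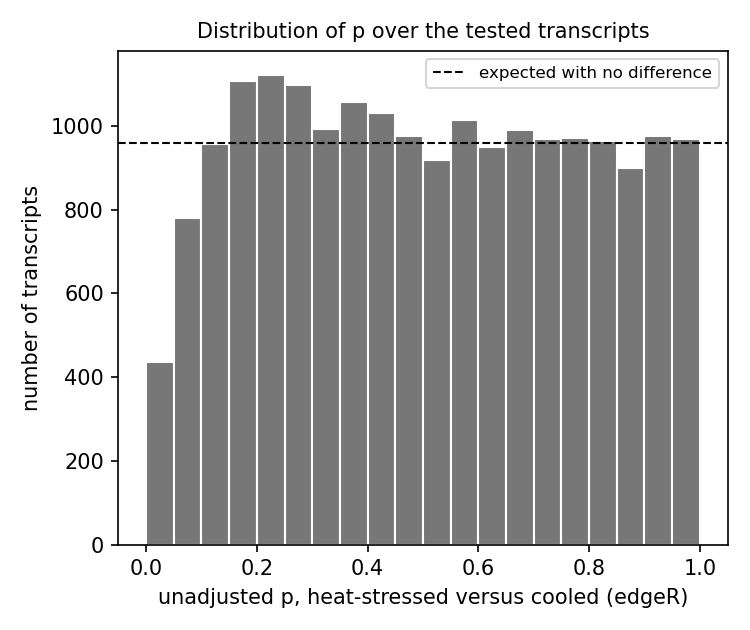
Number of tested transcripts (vertical axis) by unadjusted edgeR p for heat-stressed versus cooled libraries (horizontal axis, bins of width 0.05). The dashed line marks 959 transcripts per bin, the nominal rate with no difference. Other splits of the same libraries gave a median of 519 in the lowest bin. The lowest bin holds 436 transcripts and the next 781, both under the line.

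Precision differed with abundance. The 95% interval lay within 2-fold in both directions for 8677 transcripts (45.2%) and within 4-fold for 15084 (78.6%). Among the 3983 transcripts with a mean log2 CPM of at least 5, the interval lay within 2-fold for 3556 (89.3%), and 17 had an estimate beyond 2-fold.

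The transcripts nearest the threshold are given by ID, since the files do not pair them with gene names. ENSBTAT00000050485.4 (2628 nt) had 31.4 ± 5.26 CPM in cooled (SD, n = 7) and 54.6 ± 17.6 CPM in heat-stressed libraries (SD, n = 8). Its log2 fold change was 0.80 with a standard error of 0.22, and 7 of the 8 heat-stressed libraries lay above the cooled median. ENSBTAT00000020028.4 (4490 nt) had 7.05 ± 2.74 and 16.5 ± 7.11 CPM, a log2 fold change of 1.22 with a standard error of 0.33, and 6 of 8 libraries above that median. In the other direction, ENSBTAT00000010914.5 (5035 nt) had 11.0 ± 10.1 CPM in cooled and 2.46 ± 1.12 CPM in heat-stressed libraries, a log2 fold change of -2.16 with a standard error of 0.57. ENSBTAT00000028438.5 (1415 nt) had 16.9 ± 18.8 and 1.60 ± 1.60 CPM, a log2 fold change of -3.40 with a standard error of 0.93. All 8 heat-stressed libraries lay below the cooled median for both, and the second was at 0 in heat-stressed replicate 2, where a count of 0 allows up to 0.0646 CPM. The edgeR adjusted p was 0.996 for each of the 4 transcripts. Both lower transcripts had cooled standard deviations about as large as their cooled means.

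The most abundant feature of the files was a block of 13 consecutive transcripts, each above 0.05% of counts on average, which was singled out after its values were seen. The block took 22.0% ± 7.41 of counts in cooled (SD, n = 7) and 16.1% ± 3.10 in heat-stressed libraries (SD, n = 8). The difference was -5.87 percentage points, with an exact permutation p of 0.0598 and an adjusted p of 0.181 over 10 library measures, so it did not exceed the spread between libraries by that test. Cooled libraries ran from 10.1% in replicate 4 to 32.7% in replicate 7, and heat-stressed libraries from 11.7% in replicate 4 to 22.2% in replicate 1. Without cooled replicate 4 the difference was -7.85 points (exact permutation p = 0.00333), and without heat-stressed replicate 1 it was -6.74 points (exact permutation p = 0.0390). Without cooled replicate 7 it was -4.08 points (exact permutation p = 0.131), and without cooled replicate 3 it was -4.70 points (exact permutation p = 0.125).

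**Figure D2:**
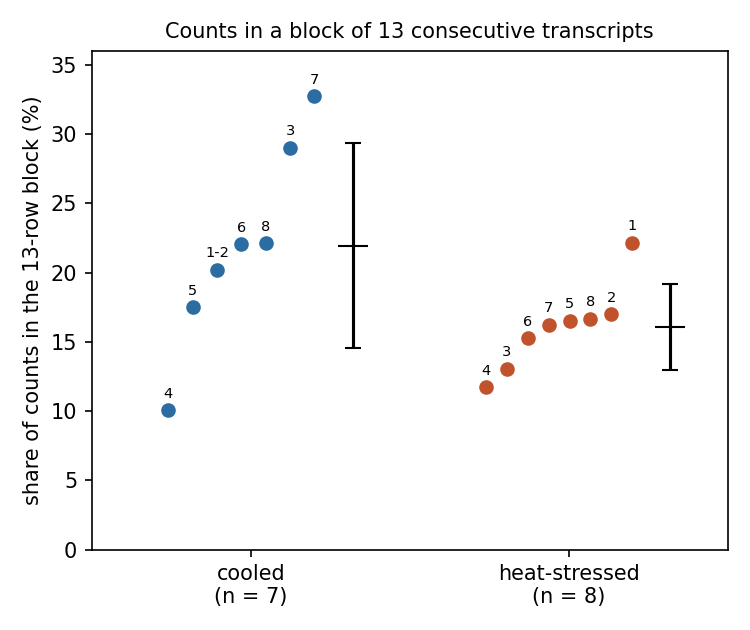
Share of each library's counts in the 13-transcript block (vertical axis, percent) for cooled (n = 7) and heat-stressed (n = 8) libraries; points are libraries with their replicate numbers, and bars give the mean ± SD. Of the cooled libraries, replicate 4 lies lowest at 10.1% and replicate 7 highest at 32.7%, while heat-stressed libraries run from 11.7% to 22.2%.

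Every one of the 13 members had a lower fitted level in heat-stressed calves, with log2 fold changes from -1.13 to -0.30 and a median of -0.86. The 13 estimates stayed negative under TMM, RLE, upper-quartile and library-size scaling, with medians from -0.86 to -0.71. Library-size scaling moved the median of all transcripts by 0.10 on the log2 scale, the largest shift. With the member nearest to 0 at -0.30, such a shift could not turn a sign, so the unchanged signs add no support. The 1378-nt member had 12764 ± 7464 CPM in cooled and 5860 ± 1926 CPM in heat-stressed libraries (SD), a log2 fold change of -1.12 with a standard error of 0.34. The 1545-nt member, the most abundant, had 84408 ± 30482 and 62445 ± 19938 CPM, a log2 fold change of -0.43 with a standard error of 0.25. For 9 of the members, all 8 heat-stressed libraries lay below the cooled median. No member passed over all tested transcripts in edgeR, and 8 of 13 had an adjusted p under 0.05 when adjusted over the block alone. These 8 are not independent evidence. The block was taken up after its abundance was seen, and its members were correlated (0.754, estimated from the data). Camera with the preset correlation of 0.01 gave p = 2.97e-08. With the correlation of 0.754 estimated from the data, it gave p = 0.0868, and fry's directional test gave p = 0.0588. Without cooled replicate 4 these p-values were 0.0102 and 0.00144, and without heat-stressed replicate 1 they were 0.0660 and 0.0454. The highest values with a library left out were 0.181 for camera, without heat-stressed replicate 6, and 0.148 for fry, without cooled replicate 3.

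Other properties of the libraries were compared in the same way. Counts in transcripts with shared-read estimates made up 43.8% ± 4.68 of cooled and 47.9% ± 2.32 of heat-stressed libraries (SD, exact permutation p = 0.0454, adjusted p = 0.181). That share ran opposite to the block share and is not a separate group difference. Cooled replicate 7, with 32.7% of counts in the block, had 37.1%, and cooled replicate 4, with 10.1% in the block, had 51.1%. The 10 most abundant transcripts, 7 of which belong to the block so that this measure overlaps with its share, took 23.5% ± 5.15 and 19.1% ± 3.03 of counts (exact permutation p = 0.0640, adjusted p = 0.181). The median correlation of a library with the others was 0.855 ± 0.0182 and 0.870 ± 0.0120 (exact permutation p = 0.0723, adjusted p = 0.181).

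The last comparison asked whether the libraries parted by gestational treatment. The first principal component held 12.2% of the variance and the second 11.0%. Group means did not differ along either by more than the spread between libraries (exact permutation p = 0.331 and 0.962). Along the first component cooled libraries ran from -41.9 to 48.8 (SD 35.3) and heat-stressed libraries from -20.1 to 23.6 (SD 13.9). Whether the groups differ in spread was not tested. Along the second component, cooled replicate 5 (46.8), heat-stressed replicate 8 (46.6) and heat-stressed replicate 2 (39.6) lay apart from the other 12 libraries, which scored 6.31 or less.

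**Figure D3:**
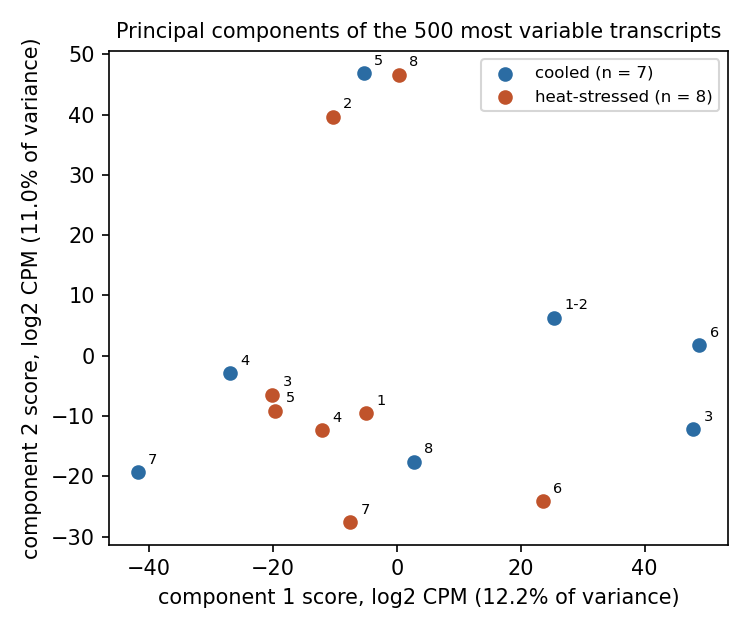
Scores of the 15 libraries on the first (horizontal axis, 12.2% of variance) and second (vertical axis, 11.0%) principal components of log2 CPM over the 500 most variable transcripts; points are libraries with their replicate numbers, colored by group. The groups overlap, with cooled libraries reaching further to both sides along the first component. Cooled replicate 5, heat-stressed replicate 8 and heat-stressed replicate 2 sit apart at second-component scores of 46.8, 46.6 and 39.6.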

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

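Dixon's test for a single distant sample was applied to 30 groups of values, and 4 had a sample past the 95% limit; chance alone gives about 1 in 20. No explanation was tested for these values themselves; an exchange of the labels of heat-stressed replicate 6 and cooled replicate 4 was tested on transcript counts and is described under the other observations. On the first principal component, heat-stressed replicate 6 scored 23.6, far above the next heat-stressed library at 0.275. On the second component, cooled replicate 5 scored 46.8 and the next cooled library 6.31. For ENSBTAT00000050485.4, heat-stressed replicate 3 had the lowest level of its group at a log2 CPM of 4.42, with the next at 5.48, so the transcript with the higher group mean was low in this library. For ENSBTAT00000010914.5, heat-stressed replicate 4 was lowest at a log2 CPM of -1.23, with the next at 0.59.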

How the results depend on the processing

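The alternatives on the block, on the identical files, on whole-number transcripts, on DESeq2 with edgeR's filter, on transcripts above 0 in at least 8 libraries, on the replicate block with the shared file as number 2, on left-out libraries for the components and on the pair of left-out libraries were chosen after the data were seen. The count of transcripts past the threshold stayed 0 in 31 of 36 alternatives. It was 57 with DESeq2 (20 higher, 37 lower), 0 with DESeq2 on the transcripts edgeR kept, 436 at an unadjusted p under 0.05 and 113 with a log2 fold change of at least 1 as well. Leaving out each library gave 0 to 1. The 1 came without cooled replicate 4 and also without both cooled replicate 4 and heat-stressed replicate 6 (1 transcript). Counts at an unadjusted p under 0.05 were 2024 without heat-stressed replicate 6, 908 without cooled replicate 4, 273 without cooled replicate 3, 279 without heat-stressed replicate 5 and 253 without heat-stressed replicate 4, and the cause was not tested by these counts. With the replicate block the count was 0 (512 unadjusted). Same-numbered libraries correlated at -0.211 to 0.127, with 2 of 8 pairs over 0.1 and 1 of 8 heat-stressed libraries closest to its own number. The block difference was negative in all 20 alternatives, from -7.85 without cooled replicate 4 to -4.08 without cooled replicate 7 when leaving out each library. Its exact permutation p, unadjusted over the library measures, was under 0.05 without cooled replicate 4, without heat-stressed replicate 1 (-6.74) and without both cooled replicate 4 and heat-stressed replicate 6 (-7.73, exact permutation p = 0.00816). Of the 4 named transcripts none reversed, which adds no support because they were picked by the smallest p in the same data. Under DESeq2 ENSBTAT00000010914.5 (adjusted p = 0.0494) and ENSBTAT00000028438.5 (adjusted p = 0.0315) passed, while over all alternatives the adjusted p ran from 0.0315 to 1. Both components kept p over 0.05 in all 17 alternatives. Alternatives on gene lists and on the list level per library were not run, because IDs could not be paired with names. At 40573338 counts or more per library, the coefficient of variation between libraries was 70.8%, and 47.9% on the whole-number transcripts alone.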

Other observations

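The identity of the block, its contrast between members, the origin of the DESeq2 calls, the splits at the adjusted threshold and both tests on cooled replicate 4 were examined only after the results were seen. The lengths of the 13 abundant transcripts equalled, 13 of 13, those of the protein-coding genes that the RefSeq table places on the bovine mitochondrial genome, and no other run of 13 rows shared more than 3. A hypothesis is therefore that the block may hold the mitochondrial messenger RNAs, which encode subunits of the respiratory chain and ATP synthase. IDs and names were not paired by any source used here. Under that hypothesis the 7 members with the lengths of ND genes had log2 fold changes of -1.13 (ND4L), -1.12 (ND4), -1.02 (ND5), -0.99 (ND1), -0.90 (ND6), -0.90 (ND2) and -0.39 (ND3), and those with the lengths of COX1, COX2 and COX3 had -0.43, -0.30 and -0.45.

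Explanations for the lower block share in heat-stressed libraries were set against each other. Depth argued the other way: group totals differed by 1.96%, the share and the total had a Spearman rho of -0.393 (permutation p = 0.151; Pearson r = -0.331, permutation p = 0.233, and -0.498 without the 2 farthest libraries), and the slope within groups would give a difference of 0.546 points where -5.87 was seen. Leaving out the 10 most abundant other transcripts kept 104% of the difference. They were only taken out of the total, which could hardly shrink the difference, so this result decides nothing about them. A length bias stayed open as a relation across libraries: share and mean transcript length of other counts had a Pearson r of -0.322 (permutation p = 0.241). Spearman rho was -0.561 (permutation p = 0.0315, adjusted 0.0630 over 2 relations), and Pearson r was -0.495 without the 2 farthest libraries. Mean length was 31.0 nt higher in heat-stressed libraries (exact permutation p = 0.654, adjusted p = 0.754). The within-group slope would give -0.400 points, so by that slope length would account for little of the difference. One common factor for all members, such as a different yield of this RNA class, also cannot be told apart from unequal change, since the ND-length minus COX-length contrast differed by -0.41 on the log2 scale (exact permutation p = 0.103); fewer mitochondrial transcripts per cell or a different mix of cell types remain untested.

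The transcript counts were compared over splits of the 15 libraries, with the real split counted among them. At the adjusted threshold the real split gave 0, so all 100 splits gave at least as many by construction and the comparison decides nothing; the highest other split gave 32. At an unadjusted p under 0.05, 54 of 100 splits gave as many as the real 436, with a highest of 3844, several times the real count, which points to a structure of the samples, although no test showed what it is. Of the 40 splits tested with DESeq2, 36 gave as many as the real 57, with a highest of 1034. Chance was not excluded for the unadjusted count or for the DESeq2 count. Of the 57 DESeq2 calls, 93.0% were above 0 in under 8 libraries, against 30.5% of all transcripts with a count, which is consistent with calls that rest on transcripts present in a few libraries.

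Cooled replicate 4 and heat-stressed replicate 6 lay on the side of the other group. Along the difference between the group means of the other libraries, over tested transcripts outside the block, cooled replicate 4 had the highest correlation towards heat-stressed of all 15 libraries (0.292) and heat-stressed replicate 6 the lowest (-0.288). A 3603-nt transcript, the one past the threshold without cooled replicate 4 and singled out after its values were seen, had 2.58 to 16.2 CPM in the 8 heat-stressed libraries and 8.92 CPM in cooled replicate 4, but at most 6 counts in each of the other 6 cooled libraries. Its log2 fold change was 2.81 with a standard error of 1.37 over all 15 libraries. A wrong label on cooled replicate 4 alone cannot be told apart from ordinary variation by this measure, since 10 of the other 14 libraries, 3 of 6 cooled and 7 of 8 heat-stressed, lay on the side of their own group. The measure leans towards the group with the steadier mean, and the cooled mean rests on fewer libraries. The counts for cooled and heat-stressed libraries are therefore not on an equal footing.

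A swap of these 2 labels is a candidate explanation. Each of the 56 exchanges of a cooled and a heat-stressed label was fitted with edgeR. Exchanging cooled replicate 4 with heat-stressed replicate 6 gave 1103 transcripts at an adjusted p under 0.05 and 4171 at an unadjusted p under 0.05. The other 55 exchanges gave at most 1 and 3952, and the 100 splits at most 32 at the adjusted threshold. The splits were drawn without a search over exchanges, whereas this pair had the most extreme side scores. The splits are therefore not a like reference, and the gap does not measure how unusual 1103 is. On the 5894 tested transcripts with whole-number estimates the same exchange gave 790. Of the 56 exchanges it also gave the widest ND-length minus COX-length contrast (-0.75, against -0.41 as labelled). That measure, taken within the block, had no part in the side scores, but its rank follows from the 2 libraries' own values. Heat-stressed replicate 6 had the highest contrast of its group (-2.22) and cooled replicate 4 the lowest of its group (-3.48). Another difference between these 2 libraries could give the same, so the contrast does not separate a swap from it. For the block share the exchange ranked 6 of 56. The pair was picked on the same expression values, and the 5 exchanges that came next in unadjusted calls all moved heat-stressed replicate 6 too. With group means removed, heat-stressed replicate 6 correlated most with cooled replicate 3 (0.421), the highest of any cooled and heat-stressed pair. Its correlations with the other cooled libraries ran from -0.314 to 0.127. With these 2 libraries left out, 876 transcripts had an unadjusted p under 0.05 in edgeR. Likeness to 1 cooled library was not told apart from a swap. A tissue or family difference that falls close to the groups by coincidence may therefore give the same counts. Of the 6435 possible splits, 57 (0.886%) lie within 1 exchange of the labels. That share counts splits and is not the probability of such a coincidence. With the labels as given and both cooled replicate 4 and heat-stressed replicate 6 left out, 1 transcript passed. That is the same count as with cooled replicate 4 left out alone, and whether the transcript was the same was not checked. Of the other 55 such pairs, 8 also gave 1, and 7 of these 8 left out cooled replicate 4. The unadjusted count without cooled replicate 4 and heat-stressed replicate 6 was 2988. It was 2633 without cooled replicate 5 and heat-stressed replicate 6, and 2324 without the shared cooled file and heat-stressed replicate 6. The median over the 56 pairs was 417, and the count was 2024 without heat-stressed replicate 6 alone. No genotype, pedigree or second measurement of these calves was used here, so the labels were kept as given throughout.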
